A study of Caenorhabditis elegans with 6 samples.

How the data were processed

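The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for ELT-3, a GATA-type zinc finger transcription factor of the C. elegans epidermis. Per the labels, whole animals of strain OP75, which carries ELT-3 fused to GFP and FLAG, were collected at the third larval stage (L3) and the chromatin was sonicated. The 6 libraries formed 1 group and came from 4 biological replicates, numbered 1, 2, 4 and 5. Replicate 2 was sequenced as 3 technical libraries and was counted once, and each other replicate was 1 library. The peak list used for replicate 2 was assigned to it from the deposited listings of its 3 libraries, which name the alignment behind that list, and the replicate 2 values rest on this assignment. Nothing in the sources used here says whether the replicates were grown as separate cultures, so the spread between them may be partly technical.

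The authors deposited peak lists in narrowPeak form for 2 genome builds, ce10 and ce11. Per the file headers of the deposited listings, each replicate list held peaks and background meant as input for the irreproducible discovery rate (IDR) procedure, 1 further list was called on the reads of all replicates pooled, and a final list, called optimal here as in the listings, held the peaks that passed the IDR threshold. Each list was called against 1 control from another experiment, which was not analysed here. The deposited signal value per peak is the strength given by the authors' peak caller. It was used only to rank peaks within 1 list. A deposited −log10 q-value per peak was also present and was used for description only. The peak caller, the aligner, their versions and the read depths are not given in the sources used here, so depth is unknown and precision is given by counts of peaks and by the spread between replicates. Before any test, the optimal list was compared with the pooled list, and its 1047 peaks on ce11 were the 1047 strongest of the 14525 pooled peaks.

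Positions and genes were taken from the WBcel235 assembly, which is the ce11 build, with Ensembl release 115 annotation. Coordinates are on ce11, counted from 1. The ce10 lists were compared only by number and chromosome, and no coordinate was converted between builds. A promoter was set as 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding transcript, and a gene was called bound when a peak summit lay in such a window. A summit in the windows of several genes counted for each. Summits outside promoters were assigned to exons, introns or other sequence, and the share in each class was compared with the share of bases by a two-sided exact binomial test. Peaks per chromosome were compared with the share of the 19973 protein-coding genes in the same way.

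Replicates were compared on their 1047 strongest nuclear peaks each. A peak was matched when another summit lay within 100 bp, and chance matches came from 100 random placements of the peaks on the same chromosomes. The rank correlation of signal values between replicates is not reported here. The GATA motif WGATAR (W is A or T, R is A or G) was searched on both strands within 50 bp of each summit and in a window of the same size centred 350 bp to the left. The 2 windows of each peak were compared by the exact McNemar test. All 2080 6-mers, each joined with its reverse complement, were tested in the same way. The relation of peak rank to presence of the motif was tested with 100000 permutations in the main setting and with fewer in the alternatives.

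The 12 gene lists were fixed before the data were examined: cuticle collagens, the furrow collagens among them, other cuticle and molting genes, epidermal regulators, genes of the osmotic and epidermal damage response, heterochronic genes, markers of intestine, body wall muscle, pharynx, neurons and germline, and ribosomal proteins. Each was tested by Fisher's exact test, two-sided, against all protein-coding genes. Gene name classes, meaning the letters before the hyphen, were tested likewise when they held 10 genes or more. Adjusted p-values follow Benjamini and Hochberg within each family, with a threshold of 0.05. Shares have Wilson 95% confidence intervals, which cover counting error only.

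The named genes followed a rule set before the data were examined. It took elt-3 and the other GATA-family genes, up to 4 members of each list with the strongest promoter peak, the gene nearest to each of the 20 strongest peaks, the 5 genes with the most promoter summits, and up to 5 name classes of lowest adjusted p. Because 19 genes tied at 2 promoter summits, the 5 with the strongest peaks were taken. tRNA genes were counted near a summit within 200 bp. The same count for snoRNA and snRNA genes was added after the data were seen.

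The alternatives tried were other promoter windows, assignment to the nearest 5′ end, other matching distances, other motif windows and backgrounds, fewer or more peaks per list, each replicate alone, and leaving out each replicate in turn. The last kept the optimal peaks found among the strongest of all the other replicates. The optimal list itself was not remade, so reads of the replicate left out still entered it. The peaks kept were therefore also those most widely shared. The functions were tested on simulated data. Lists of 20 genes with 5 planted bound members were found in 100 of 100 simulations, but lists with 1 planted member in only 3 of 100. A planted TGATAA was found when it stood in 10 percent or 30 percent of the simulated windows but not at 5 percent, and 0 of 2080 6-mers were called when none was planted. The simulated centre and flank windows had the same base composition, unlike those of the data, so calls due to composition were not checked. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.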

Results

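ELT-3 occupancy was mapped in L3 larvae with a GFP-FLAG tagged protein in 4 biological replicates of 1 group. The optimal list held 1047 peaks on ce11, with a median width of 336 bp and signal values from 39.9 to 234. Each replicate list held 30000 peaks and background regions. With 1 group and no second condition, the data answer where peaks lie, at which genes, on which sequences and how far the replicates share them.

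The list with the most bound genes was the ribosomal proteins, the structural components of the ribosome, with 25 of 76 genes carrying an optimal peak summit in a promoter. By the share of all genes bound, 2.25 would have been expected. The number was 15, 22, 20 and 24 in the strongest peaks of replicates 1, 2, 4 and 5 (mean 20.2 ± 3.86, SD, n = 4). Among these genes were rpl-3, with the second strongest peak of the list (signal 225, III, 3867499 to 3867681, 272 bp upstream of the 5′ end), rpl-15 (signal 163), rpl-35 (signal 146) and rps-12 (signal 121). All 4 of these peaks were among the strongest peaks of all 4 replicates. The odds ratio was 16.8 (Fisher's exact test, adjusted p = 8.0e-19 over the 12 lists). Only 3 of the 23 peaks behind this count held a GATA motif within 50 bp. The list took only names with digits and points after rpl- or rps-, so it left out rpl-7A, whose promoter peak (signal 78.8) held the motif. Counting only the nearest 5′ end within 1000 bp left 13 bound genes and an odds ratio of 7.66, and among genes with an upstream gap of at least 1000 bp the odds ratio was 12.1 on only 2 bound genes, too few for the call (adjusted p = 0.0726, Fisher's exact test). Leaving out each replicate in turn gave odds ratios from 29.2 to 44.8. These rested on fewer genes, with 10, 9, 10 and 8 ribosomal protein genes bound without replicates 1, 2, 4 and 5, among 75 to 109 bound genes in all.

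Genes of the epidermis and its cuticle were bound in small numbers that did not pass the adjusted threshold. Among epidermal regulators, elt-3 itself, nhr-25 and nhr-23, which encode a GATA factor and nuclear hormone receptors of molting, made 3 of 19 (expected 0.561, odds ratio 6.19, Fisher's exact test adjusted p = 0.0699). The nhr-23 peak was among the strongest peaks of 0 of the 4 replicates. Of the 6 furrow collagens, whose loss shortens the body, dpy-10 (signal 75.2, 375 bp upstream) and dpy-2 (signal 63.9, 252 bp upstream) were bound, both with a GATA motif at the peak (odds ratio 16.5, Fisher's exact test adjusted p = 0.0699). The dpy-10 summit lay nearer to the 5′ end of another gene. The 2 genes lie near each other on II on opposite strands, with summits at 6712602 and 6714040. Fisher's exact test counts them as separate genes, so it does not allow for their sharing 1 region. In the osmotic and epidermal damage list, 3 of 23 genes were bound (Fisher's exact test adjusted p = 0.0878). These were the antimicrobial peptide genes nlp-31 and nlp-34, which share 1 peak of signal 98.2 on V, and osm-11 (signal 47.9). For a promoter of 500 bp upstream to 100 bp downstream, the furrow list and the epidermal regulators both passed (Fisher's exact test, adjusted p = 0.0277 for each). For the window from 2000 bp upstream to 500 bp downstream, the epidermal regulators passed with 0.00551 and the furrow list did not (0.0709). Leaving out each replicate in turn left 1 bound epidermal regulator, elt-3, with adjusted p-values from 0.276 to 0.425 (Fisher's exact test). The stronger elt-3 peak was among the strongest peaks of all 4 replicates, and the nhr-25 peak of only 2. Because elt-3 is the tagged gene, extra copies of its region carried by the transgene could contribute to its peaks. The list was not tested without elt-3. Without replicate 4 or replicate 5, 0 furrow collagens were bound, and the osmotic and damage list had 0 bound genes whichever replicate was left out. These sets kept only 110 to 169 peaks, so lists resting on few peaks could lose them through the smaller number alone. In the strongest peaks of replicates 1, 2, 4 and 5 alone, 2 furrow collagens were bound each time. The furrow list then passed (Fisher's exact test, adjusted p = 0.0216, 0.0327, 0.0460 and 0.0420). The osmotic and damage list had 4, 3, 3 and 4 bound genes and passed in replicates 1 and 5.

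The cuticle collagens as a whole, 174 genes that encode the main proteins of the cuticle, held 7 bound members against 5.14 expected (odds ratio 1.38, Fisher's exact test adjusted p = 0.625). The strongest were at dpy-10, dpy-2, sqt-1 (signal 60.9) and dpy-13 (signal 45.4). Of 32 other cuticle and molting genes, 2 were bound, dpy-11 (signal 74.9) and the protein disulfide isomerase gene pdi-2 (signal 46.1), with an adjusted p of 0.488. Among 9 heterochronic genes, which time larval development, lin-42 was bound (signal 59.6, Fisher's exact test adjusted p = 0.488). None of the 24 intestine, 20 body wall muscle, 13 pharynx, 23 neuron or 24 germline marker genes had an optimal peak in a promoter, and all 5 adjusted p-values were 1. Fewer than 1 bound gene was expected in each of these 5 lists, so a lower share than in other genes was not detectable. In all, 590 protein-coding genes (2.95%) were bound, and 107 of the 493 promoter summits lay in promoters of 2 or more genes.

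**Figure D1:**
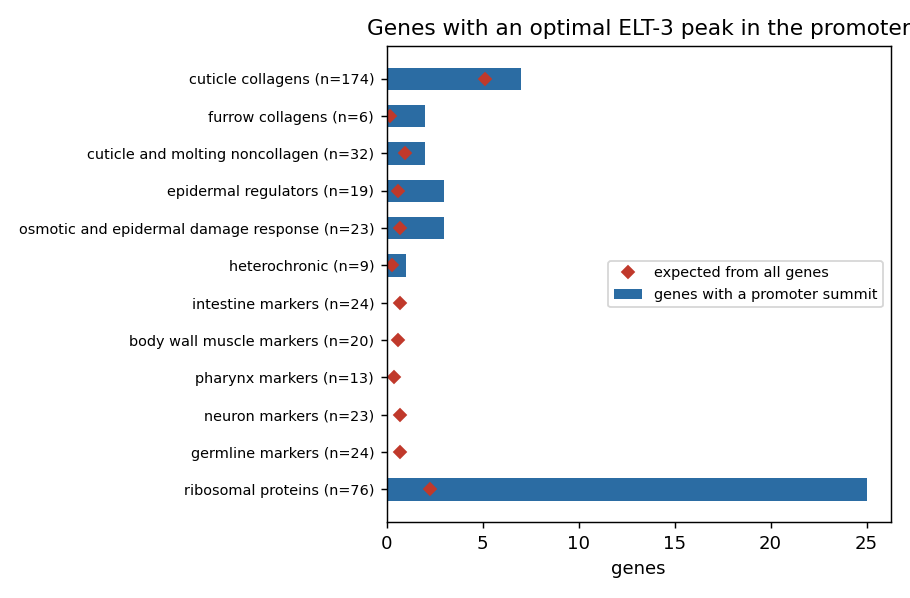
Number of genes in each fixed list with an optimal ELT-3 peak summit in the promoter (bars, in genes) and the number expected from the share of all genes bound (diamonds). The ribosomal proteins had 25 bound genes against 2.25 expected, and the 5 marker lists of other tissues had 0.

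Gene name classes gave 4 of 175 past the threshold, all with more bound genes than expected. The large ribosomal subunit class rpl had 15 of 47 genes bound (adjusted p = 5.2e-10), and the small subunit class rps 11 of 31 (5.9e-08), both by Fisher's exact test. The sec class had 5 of 19 (Fisher's exact test, adjusted p = 0.0106), with the translocon genes sec-61.G (signal 117), sec-61.B and sec-61.A, the COPII coat gene sec-24.1 and the exocyst gene sec-15. The dpy class, named for a short body, had 5 of 25 (Fisher's exact test, adjusted p = 0.0315), of which dpy-10, dpy-2 and dpy-13 encode collagens. With the nearest 5′ end only, 2 of the 11 rps genes were still counted and its adjusted p was 1. The sec call was lost in 9 of 14 alternatives and the dpy call in 10 of 14, including each one that left out a replicate. The classes were not fully separate, because some summits counted in more than 1. The summit counted for sec-61.A was also that of rps-18. Likewise, rpl-39 shared its summit with rps-30, and rpl-24.1 with rps-10.

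At elt-3 itself (X, 13934874 to 13941216, plus strand), 2 optimal summits lay in promoters of alternative 5′ ends, both in introns of the longer transcripts. The stronger one ranked 175 with a signal of 72.4, held a GATA motif and was among the strongest peaks of all 4 replicates. In the 40 kb centred on the gene there were 7 optimal peaks. The median 40 kb window of the genome held 0. No optimal summit lay in a promoter of the other GATA-family genes elt-1, elt-2, elt-4, egl-18, elt-6, elt-7, end-1, end-3, med-1 and med-2.

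**Figure D2:**
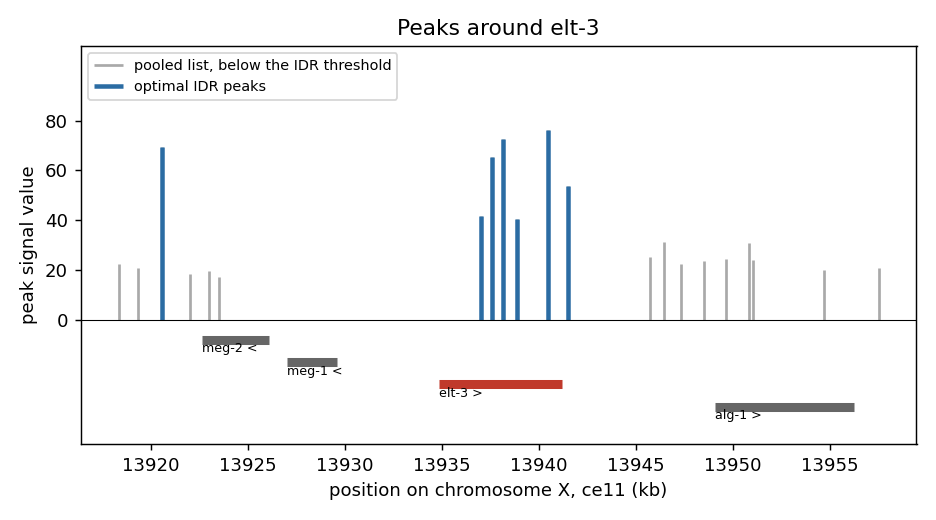
Peaks around elt-3 on chromosome X (position in kb on ce11, peak signal value upward), with optimal peaks in blue, other pooled-list peaks in grey and protein-coding genes as bars below. Optimal peaks lie within and just beyond the gene, with 1 more at 13920588.

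The 20 strongest peaks were shared between replicates, each being among the strongest peaks of all 4. The strongest of all (IV, 13919319 to 13919504, signal 234) was intergenic, at −6365 bp relative to the nearest 5′ end, that of Y37A1A.2, and held a GATA motif. Peaks in promoters were those nearest to rpl-3, tasp-1 (signal 224), cdc-48.1, which encodes a AAA ATPase (signal 194), the Pumilio gene puf-9 (signal 169), nspc-17, rpl-15, the initiation factor gene iff-2 (signal 150), rpl-35 and egg-5. The egg-5 peak lay within 200 bp of the spliced leader RNA gene sls-2.4. The other strong peaks lay outside promoters, nearest to W02H3.3, F55G7.5, K02D3.1, C41A3.2, mom-1, ZK899.6, F19H6.5, B0334.20, Y41G9A.17 and F20B6.9. Among these, the C41A3.2 peak lay in a coding exon of pks-1 and the mom-1 and Y41G9A.17 peaks in introns. GATA motifs were present in the peaks nearest to Y37A1A.2, mom-1, ZK899.6 and F19H6.5. Among the 19 genes with 2 promoter summits, those with the strongest peaks were H41C03.3 (signal 122), the G protein gene egl-30 (signal 98.4), nhr-80 and its divergent neighbour H10E21.1 (signal 96.9, shared) and kin-14 (signal 85.9).

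Summits were concentrated in promoters and rare in exons. Of the 1047 summits, 493 (47.1%, 95% CI 44.1 to 50.1) lay in promoters, which make up 26.1% of bases (exact binomial test, adjusted p = 2.0e-47). Exons outside promoters held 54 summits (5.16% against 21.7% of bases, exact binomial test adjusted p = 5.8e-50) and introns 186 (17.8% against 27.1%, adjusted p = 2.3e-12). The intron deficit was not past the threshold without replicate 5 (ratio 0.725, exact binomial test adjusted p = 0.118). The remaining 314 (29.99%) lay in other sequence, 25.1% of bases (exact binomial test, adjusted p = 3.1e-04). The median distance to the nearest 5′ end was 856 bp, and 64.5% of summits were upstream of it. The promoter share of the strongest peaks was 36.2%, 39.4%, 47.3% and 45.3% in replicates 1, 2, 4 and 5 (mean 42.0% ± 5.14, SD, n = 4). Exon shares were 19.1%, 16.1%, 4.39% and 4.58%, and the exon depletion did not pass the threshold in replicate 1 alone (exact binomial test, adjusted p = 0.0571). The excess in other sequence (ratio 1.197) did not pass the threshold when each replicate in turn was left out. Ratios were then 1.104 to 1.26 (exact binomial test, adjusted p-values from 0.0658 to 0.514). Those sets kept only 110 to 169 peaks, so this does not show that the excess was absent.

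The X chromosome carried more peaks and chromosome V fewer than their genes would give. X held 250 peaks (23.9%, 95% CI 21.4 to 26.6) with 13.7% of protein-coding genes and 17.7% of bases (exact binomial test against genes, adjusted p = 4.6e-18). The X share was 20.8%, 21.8%, 25.02% and 23.1% in the 4 replicates (mean 22.7% ± 1.82, SD). V held 148 peaks (14.1%), 0.565 times the number its genes would give (exact binomial test, adjusted p = 2.6e-17), and 0.357 to 0.497 times without each replicate in turn. Chromosome I held 186 peaks (17.8% against 14.4% of genes, exact binomial test adjusted p = 0.0055), a difference lost among the 523 strongest peaks (0.0920), in replicate 5 alone (0.318), and in the peaks also strong in replicates 4 and 5 (0.0564, a setting chosen after the data were seen). It was also lost without replicate 2, without replicate 4 and without replicate 5 (exact binomial test, adjusted p = 0.453, 0.414 and 0.504). Chromosomes II, III and IV were not past the threshold, with adjusted p-values of 0.870, 0.778 and 0.156. A deficit on IV passed in replicate 1 alone, in replicate 4 alone, without replicate 1 and against the share of bases (exact binomial test, adjusted p = 0.0035, 0.011, 0.041 and 0.023).

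GATA motifs, the sequence that GATA factors recognise, were concentrated at the summits. WGATAR occurred within 50 bp of 413 summits (39.4%, 95% CI 36.5 to 42.4) and in 236 flank windows (22.5%). The motif was in the centre only at 316 peaks and in the flank only at 139 (exact McNemar test, p = 6.4e-17). The centre share was 27.9%, 27.7%, 44.0% and 43.6% in replicates 1, 2, 4 and 5, with flank shares between 21.2% and 22.9%. The difference of centre and flank was above 0 in 4 of 4 replicates (mean 13.7 points ± 9.29, SD, n = 4), with exact McNemar p-values of 5.4e-04, 0.013, 2.6e-27 and 1.6e-25. GC content was 44.3% in centre windows and 35.5% in flanks. Against centre windows shuffled with their dinucleotide counts kept, of which 18.9% held the motif, the difference was 20.5 points.

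**Figure D3:**
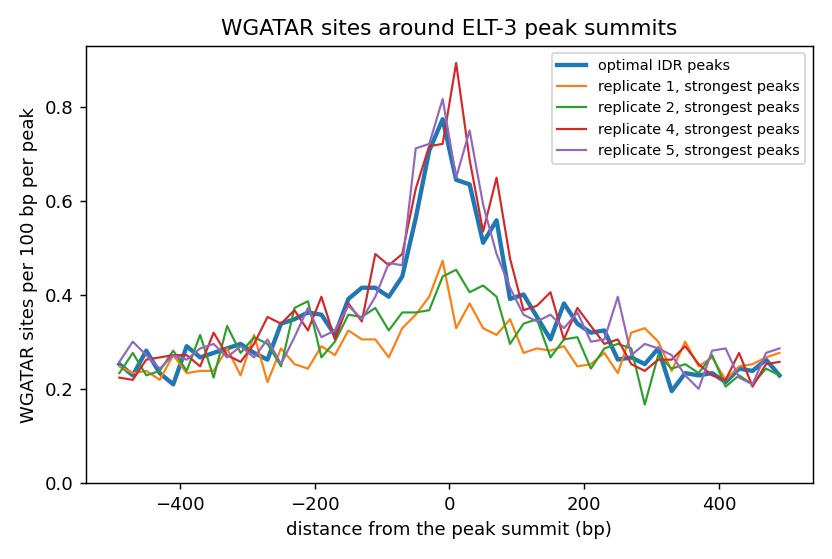
WGATAR sites per 100 bp per peak (vertical axis) against distance from the summit in bp, in bins, for the optimal peaks and the 1047 strongest peaks of each replicate. Sites were densest near the summits, with higher densities in replicates 4 and 5 than in replicates 1 and 2.

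**Figure D4:**
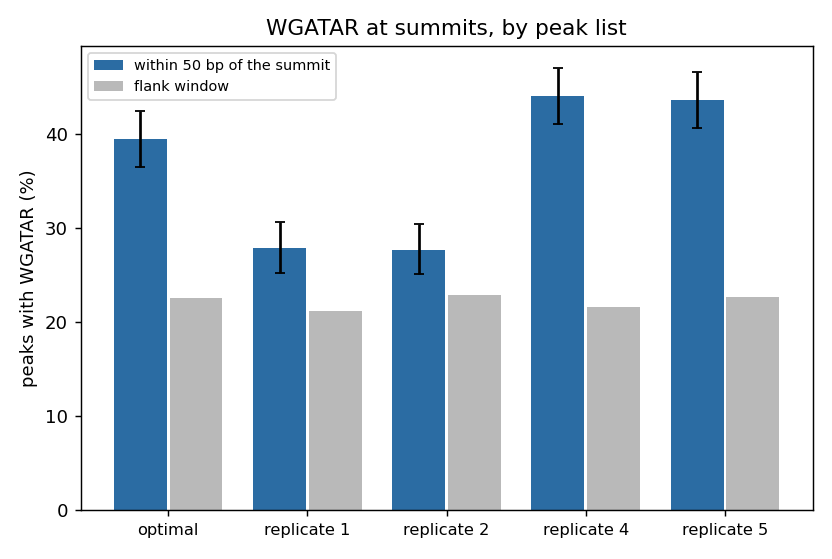
Percent of peaks with WGATAR within 50 bp of the summit (blue, with Wilson 95% confidence intervals) and in the flank window (grey) for each list. The centre share was 39.4% in the optimal list and lay between 27.7% and 44.0% in the replicates.

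Of 2080 6-mers, 401 were more frequent at summits than in flanks and 262 less frequent at an adjusted p below 0.05. Among the more frequent ones, the lowest adjusted p was that of CTTATC, whose reverse complement GATAAG is a GATA site, in 20.7% of centres and 4.39% of flanks (exact McNemar test, adjusted p = 7.9e-28). TGATAA stood in 25.6% and 9.65%. The others near the top included the GA repeat GAGAGA (20.8% against 6.11%) and the GC-richer ACGCAG (11.7% against 1.53%) and CGTCTC (13.7% against 2.96%). Of the 262 less frequent 6-mers, 149 held 5 or 6 A or T bases, next to the higher GC content of the centres.

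Stronger peaks did not hold the GATA motif detectably more often than weaker ones within the optimal list. In 5 rank groups of near-equal size, from the strongest to the weakest, the share was 41.9%, 41.4%, 37.3%, 40.7% and 35.9%. Across peaks, Spearman's rho of rank and presence was −0.0383 (permutation test, p = 0.215). For TGATAA alone, a setting chosen after the data were seen, rho was −0.0889 with permutation p = 0.0048.

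Summits lay near tRNA genes more often than random placement gave. Within 200 bp of a tRNA gene there were 44 summits (4.20%), against a mean of 3.23 and a highest of 8 in 100 placements. In the strongest peaks of replicates 1, 2, 4 and 5 the number was 16, 30, 39 and 43 (mean 32 ± 11.97, SD, n = 4). Of the 44 summits, 5 held a GATA motif. tRNA genes occur in near-identical copies, and how reads were placed among them is not given in the sources used here, so single tRNA genes are not named.

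Replicates 4 and 5 shared more of their strongest peaks with the optimal list than replicates 1 and 2. The strongest peaks of replicates 1, 2, 4 and 5 matched 31.4%, 35.2%, 61.7% and 58.4% of the 1047 optimal peaks (mean 46.7% ± 15.6, SD, n = 4), where random placement gave at most 0.764%. The optimal list was derived from these replicates, so a match is not independent of it. At least 2 replicates matched 637 optimal peaks (60.8%), all 4 matched 95, and 88 were matched in none. Between pairs, replicates 4 and 5 shared 43.8% of their strongest peaks, replicates 1 and 2 15.1%, and the other pairs 19.6% to 23.8%. Read depth per replicate is unknown.

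The lists on the 2 builds were near in size. The optimal list had 1047 peaks on ce11 and 1051 on ce10, and the pooled lists had 14525 and 14510. Chromosome X held 250 and 248 optimal peaks, and V held 148 on both.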

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

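Of 28 quantities compared across the 4 replicates, 6 had 1 replicate far from the other 3. For continuous values, chance alone gives such a gap in about 1 of 20 quantities. That rate does not hold for small counts, and 5 of the 6 are small counts in which a single gene sets the gap. Replicate 5 listed 14 mitochondrial peaks among its 30000, and the other replicates listed 0. The 14 is also above a fixed limit of 3 counts used for flagging, which rests on no model of absent signal. These peaks were not used in any comparison. The highest ranked 1 in that list, their median rank was 34.5, and their summits lay between positions 1008 and 9082 of the mitochondrial chromosome.

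Among the gene lists, replicate 2 had 3 bound genes of the other cuticle and molting genes where each other replicate had 2. Replicate 4 had 2 heterochronic genes where each other replicate had 1. Replicate 1 had 0 intestine marker genes where each other had 1. Replicate 2 had 1 body wall muscle marker gene and replicate 1 had 1 germline marker gene, where the others had 0.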

How the results depend on the processing

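The setting that kept peaks also among the strongest of both replicates 4 and 5, and the motif windows in the test of rank, were chosen after seeing the data. For the 13 results past the threshold in the main setting, 131 of 169 values under alternatives kept their direction and side, 35 were no longer past it and 3 changed direction. The cause of the changes was not tested, except that leaving out a replicate left 110 to 169 peaks. Depth is unknown and its limits could not be given. No paired analysis was possible because there is 1 group. The promoter excess, the excess on X, the deficit on V and the GATA difference kept their direction and side in each alternative run.

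Without each replicate in turn, the ratio was 0.570 to 0.725 for introns, 1.104 to 1.26 for other sequence, 1.14 to 1.44 for chromosome I, 0.623 to 0.788 for II (main value 0.985), 1.12 to 1.44 for III (main value 0.961), 0.612 to 0.870 for IV and 0.357 to 0.497 for V. Odds ratios were 0 to 1.15 for cuticle collagens, 0 to 40.1 for furrow collagens and 0 to 5.92 for other cuticle and molting genes. Those of epidermal regulators were 10.2 to 14.9 (main value 6.19), each on 1 bound gene, elt-3. Osmotic and damage genes had 0 to 0 and heterochronic genes 0 to 33.6. The classes past the threshold were 2 to 2, with an odds ratio of 0 to 16.1 for dpy, 30.9 to 42.1 for rpl, 27.99 to 67.2 for rps and 14.9 to 31.2 for sec.

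For positions, the exon ratio was 0.881 in replicate 1 alone. The ratio for other sequence was 1.05 in replicate 1 alone, 0.934 in replicate 2 alone and 1.11 with the promoter from 2000 bp upstream. For chromosome I it was 1.22 in the 523 strongest peaks, 1.11 in replicate 5 alone and 1.25 in the peaks also strong in replicates 4 and 5. For IV it was 0.791 in replicate 1 alone, 0.814 in replicate 4 alone and 0.832 against bases, each past the threshold. For II it was 1.12 against bases. For III it was 1.03 in replicate 4 alone and 1.02 in the peaks also strong in replicates 4 and 5.

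The lists past the threshold numbered 1 in the main setting, 2 in the 523 strongest peaks, 4, 3, 3 and 3 in replicates 1, 2, 4 and 5 alone, 2 in the peaks also strong in replicates 4 and 5, 3 and 2 with the shorter and longer promoter, 4 with the nearest 5′ end and 2 among genes with an upstream gap of 1000 bp. Furrow collagens then passed with odds ratios of 33.8 in the 523 strongest peaks, 23.1, 20.3, 16.9 and 17.8 in replicates 1, 2, 4 and 5 alone, 40.2 in the peaks also strong in replicates 4 and 5, 23.4 with the shorter promoter, 18.2 with the nearest 5′ end and 72.8 with the gap, on 2 bound genes each. With the nearest 5′ end these were dpy-2 and dpy-7, without dpy-10, and dpy-7 was not bound in the main setting. Epidermal regulators passed with 8.68, 10.9 and 9.05 in replicates 1, 2 and 4 alone, 8.81 and 8.19 with the shorter and longer promoter, 9.75 with the nearest 5′ end and 9.12 with the gap. Osmotic and damage genes passed with 9.77 and 7.50 in replicates 1 and 5 alone, and other cuticle and molting genes with 5.22 with the nearest 5′ end. Ribosomal proteins had 12.1 with the gap, no longer past the threshold. In replicates 2, 4 and 5 alone the intestine markers had 1.76, 1.47 and 1.54, muscle markers had 2.13 in replicate 2 alone and germline markers 2.00 in replicate 1 alone, each on 1 gene. Heterochronic genes had 0 in the peaks also strong in replicates 4 and 5.

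The classes past the threshold were 2 in replicate 1 alone, 2 in replicate 4 alone, 2 with the nearest 5′ end and 0 with the gap. For TGATAA only, rho of rank and motif was −0.0889. The tRNA share was 2.84% in the peaks also strong in replicates 4 and 5. With the right flank, 427 6-mers were more frequent at summits, 317 of them shared with the 401.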

Other observations

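The tests of sequence at ribosomal protein peaks, of mislabelled replicates, of the elt-3 region, of small RNA genes and of peaks without the motif on X, and the test of unmatched peaks against their flanks, were chosen after the results were seen. GATA motifs continued below the IDR threshold. The next 1047 peaks of the pooled list held WGATAR at 36.2% of summits and 21.3% of flanks, a difference of 14.9 points (exact McNemar test, adjusted p = 5.7e-13 over 14 blocks of the list). The block after that had 10.5 points (exact McNemar test, adjusted p = 1.0e-07). The block from rank 3142 to 4188 did not pass the threshold, the next did, and from rank 5236 on no block passed. The optimal list may therefore leave out further sites of the same kind.

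The share of summits with a GATA motif was somewhat higher outside promoters. Of 554 summits outside promoters, 42.6% held the motif, against 35.9% of 493 in promoters (odds ratio 1.32, Fisher's exact test, unadjusted p = 0.0312). Neither class was compared with its own flank or shuffled windows, so a difference in base composition was not accounted for. On X, 36.8% of peaks held it, against 40.3% on the autosomes (odds ratio 0.863, Fisher's exact test p = 0.336). The excess on X was also present in peaks without the motif, 24.9% of which lay on X (exact binomial test p = 4.2e-14), so GATA-bearing peaks alone do not make it up. Summits also lay near snoRNA genes (46, against a mean of 2.21 in random placements) and snRNA genes (17, against 0.62). Together with tRNA genes, these 107 peaks held the motif in 10.3%, against 42.8% of the other peaks (odds ratio 0.153, Fisher's exact test p = 2.6e-12), which is consistent with signal there that does not depend on a GATA site.

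The first pattern weighed is the binding at ribosomal protein promoters. Peaks there held WGATAR in 3 of 23, against 410 of 1024 other optimal peaks (odds ratio 0.225, 95% interval 0.0425 to 0.765, Fisher's exact test p = 0.00862), below the flank share of 22.5%. A candidate explanation is signal at active, accessible promoters that does not depend on a GATA site, but neither activity nor accessibility was measured. Counting summits for neighbouring genes stays open as part of the cause, because the odds ratio with the nearest 5′ end was 7.66 with an interval of 3.84 to 14.2, and the bound genes fell from 25 to 13. No biological explanation was tested.

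The second pattern is that the GATA share at the strongest peaks differed between replicates. A wrong label with no ELT-3 signal in replicates 1 and 2 stays open: 48.5% and 49.5% of their strongest 200 peaks matched the strongest peaks of replicate 4, but sites that need no ELT-3 would match too. Weaker enrichment in replicates 1 and 2 may contribute: their peaks matched in replicate 4 or 5 held the motif more often than the rest, with odds ratios of 1.504 (p = 0.0094) and 1.65 (p = 5.9e-04, both Fisher's exact test). Peaks matched to lists rich in the motif would hold it more often under either explanation, so these odds ratios separate neither. Weaker enrichment also stays open because the lower odds ratio lies at the bound of 1.5, which was written before this test was run but put in its form per replicate after other results had been seen, and the unmatched peaks of replicate 1 still held the motif more often than their flanks (25.7% against 19.9%, exact McNemar p = 0.0093), while those of replicate 2 were near their flanks (24.5% against 22.3%, p = 0.350). Read depth is unknown, and no biological explanation was tested.

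The third pattern is the cluster of peaks at elt-3. The 40 kb window centred on the gene held 21 pooled-list peaks, more than 99.6% of 10006 such windows, and 31, 36, 25 and 33 peaks in replicates 1, 2, 4 and 5, where the median window held 11 or 12. Extra copies of the region carried by the tagged transgene are a candidate explanation, but neither the extent of the transgene nor whether the control carried it was known here, and dense binding would give the same count. Binding at GATA sites cannot be told apart from this, since 3 of the 7 optimal peaks held the motif (odds ratio 1.15, interval 0.168 to 6.85, Fisher's exact test p = 1). Peaks in this window were kept in all counts.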
